A study of Mus musculus with 36 samples.

How the data were processed

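The data are single-neuron transcriptomes from the mouse midbrain. Each of 36 libraries is 1 neuron, and the letter in its title names the clone it belongs to. A clone here is the set of neurons descended from 1 radial glia progenitor, marked by MADM (a recombination method that colours the daughters of single dividing cells) on embryonic day 12. The 18 clones hold 2 sequenced cells each. In 11 clones (22 cells) the recombinase was driven by Fz10-CreER and in 7 clones (14 cells) by Sox2-CreER. By tissue label, 22 cells came from sSC and 12 from dSC, read here as the superficial and deep superior colliculus. The remaining 2 came from PAG, read as the periaqueductal grey.

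The libraries were made from polyadenylated RNA with the SMART-Seq Single Cell PLUS kit, per the labels' protocols. STAR 2.7.9a, R 4.0.3 and the genome build GRCm39 are named in the submitters' processing notes. The counting program, the annotation release, the use of strand and the formula of the values are not given in the sources used here. The deposited table holds an expression signal per gene and cell, which the authors named TPM of exon plus intron. It has 55359 genes and 36 cells. Every cell sums to 2000000, which is what an exon TPM added to an intron TPM would give, so the values were treated as a normalised signal and not as plain TPM. The plan had assumed plain TPM, and the tests fixed for it, on a log scale, serve this unit as well. The values keep no read depth. Depth per library is therefore unknown, no counting interval is given, and the number of genes at a value of 1 or more stands in as the measure of library quality. A gene listed at 0 can be a failed capture, since genes that neurons commonly use are also listed at 0 in some cells.

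Gene symbols came from GENCODE M21, an annotation of an older build, matched on the gene identifier without its version. A symbol was found for 52083 genes, and for 30717 of the 31169 genes above 0 in any cell. The same annotation gave intron lengths, gene types and overlapping genes, and no positions were taken from it. For some named genes an overlap with another gene on the opposite strand is given, because reads from both cannot be told apart without strand. Other named genes can have such overlaps too.

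Values were transformed as log2(value + 1), and genes at 1 or more in at least 25% of the cells of a comparison were tested. Differences are on that scale, which understates the difference of low genes. Cells of the same clone and tissue were averaged, so that the clone is the replicate. The labels name no animals, and several clones can come from 1 animal. The p-values therefore describe the spread between clones, and clone, animal and day of collection cannot be separated. Tissues and drivers were compared with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust), with Benjamini-Hochberg adjustment and a threshold of 0.05. The sSC and dSC fit used 16 and 11 clone means, and the driver fit in sSC used 11 and 5. The interaction fit used all of these means. The clone effect was limma's moderated F test over 16 clones with tissue as a covariate. Gene lists fixed in advance were tested with camera at a preset correlation of 0.01 where at least 3 members were measured, with camera at an estimated correlation, and with fry.

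Transmitter balance of a cell is the mean log2(value + 1) of Gad1, Gad2 and Slc32a1 minus that of Slc17a6. Single values were compared by two-sided permutation tests with 100000 resamples, and the sibling tests reassigned cells to clones within tissue and driver. The check of sex reassigned them without regard to either and was one-sided. The 9 clones with a cell in each tissue were also tested by two-sided exact sign flips. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for these.

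Siblings of a clone come from 1 animal by the design, so the letter pairs cells of different tissue, and fits with clone as a block are given for the tissues and the interaction. As a check chosen after the data were seen, Eif2s3y, a gene of the Y chromosome, was above 0 in both siblings or in neither in 18 of 18 clones. The sex call set in advance, from Xist and 4 Y-linked genes, matched in 14 of 18. Sibling deviations from the tissue means correlated between -0.049 and 0.049, with 0 of 9 pairs above 0.1, and 1 of 36 cells had its sibling as the best match.

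Named genes follow a rule. For each comparison it takes up to 12 genes per direction past the threshold, or, where fewer than 12 pass in all, the 6 per direction with the smallest p, named as not passing. It adds up to 4 members per list that pass when adjusted over the list alone, the 15 genes of smallest p for the clone effect, and a fixed set of sex-linked, transmitter and driver genes. Some results that the rule or a list would give are not reported here. The groups, tests, lists, this rule and most alternatives were set before the data were examined. The alternatives changed the pseudocount (0.1 and 10), the filter, the normalization, the eBayes options, the covariates, the block and the clones used. After the data were seen, further alternatives removed the 32 gene models that take 1% or more of a cell, left out the library with the fewest genes (for the lists also with an estimated correlation), used the block for the interaction, and joined the block with either of these or with the number of genes detected. The association of genes with transmitter balance and the check on Eif2s3y alone were also added then.

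The fits were tested on simulated data. In the tissue comparison (14613 genes) 67.2% of genes changed 8-fold and 98.5% of genes changed 32-fold were recovered, with 7 false calls. In the driver comparison (14320 genes) these shares were 35.8% and 68.7%, with 14 false calls. The clone test (15132 genes) recovered 42% of genes simulated with a sibling correlation of 0.9, with 12 false calls. The sibling test called 2 of 50 data sets without an effect and 50 of 50 with one. The size of that simulated effect is not stated, so 50 of 50 does not show how small a sibling effect the test could miss. The test on transmitter balance (14898 genes) recovered 75% of genes given a slope of 0.3 and 99% at 0.5, with 6 false calls. Slopes were given only to genes of higher mean expression, and each gene was shuffled on its own. These shares therefore do not cover low genes or genes that vary together. In these gene tests many genes were changed in the same run, for example 67 by 8-fold for the tissues. Many changed genes make the adjusted threshold easier to reach, so the shares do not carry over to a few changed genes. In the real tissue fit without the block, Lst1 differed by about 32-fold and did not pass. The 2 PAG cells entered the sibling and balance tests and were left out of the tissue fits.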

Results

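The 36 neurons carried strong neuronal expression and mixed transmitter markers. Snap25, a synaptic vesicle fusion protein, had values from 299.8 to 4008 across the cells. The number of genes at a value of 1 or more ran from 2661 to 16769, with a median of 12058, and the cell with the fewest (clone B, sSC) lay well below the next at 6180. Over clone means, sSC cells had 10541 ± 3324 such genes (SD, n = 16) and dSC cells 12081 ± 2379 (SD, n = 11), a difference of -1541 (permutation p = 0.2). Within the 9 clones with a cell in each tissue, the sSC sibling had -2868 genes relative to the dSC sibling, with 2 of 9 clones higher in sSC (exact p = 0.0312). Without the clone B pair this was -2029 (exact p = 0.0625). A group of 32 gene models, with Gm17711 the largest at up to 40.6%, took between 16.3% and 65.9% of the summed values of a cell, with a median of 33.01%.

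The first question was which transmitter each neuron uses. Slc17a6, the vesicular glutamate transporter of midbrain excitatory neurons, reached a median of 90.1 over the 36 cells. Gad1 and Gad2, the enzymes that make GABA, reached medians of 216 and 154. All 3 were high in few cells together. At a value of 100 or more, 11 cells had Slc17a6 without Gad1 or Gad2, 19 had Gad1 or Gad2 without Slc17a6, 5 had both and 1 had neither. This depended on the cut. At a value of 10 or more, 27 cells had both, 2 had Slc17a6 alone and 7 had Gad1 or Gad2 alone. At a value of 1 or more, 30 cells had both, so lower levels of the other transmitter's marker were common. Slc32a1, the vesicular GABA transporter, was at 1 or more in 24 cells with a maximum of 72.2. Slc17a7, the cortical vesicular glutamate transporter, was at 1 or more in 31 cells but did not exceed 75.4, and Slc17a8 was at 1 or more in 2 cells. Slc6a5, the glycine transporter, was at 1 or more in 15 cells with a maximum of 53.8. Slc17a6 and Gad1 ran opposite across cells (Pearson r = -0.638, permutation p = 9e-05, and Spearman rho = -0.764, permutation p = 1e-05, the smallest that 100000 permutations can give). The Pearson value was -0.651 in the 22 sSC cells and -0.719 in the 12 dSC cells, and -0.638 without the 2 cells farthest from the median of Slc17a6. It was the only relation between markers computed, and siblings entered it as separate cells.

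**Figure D1:**
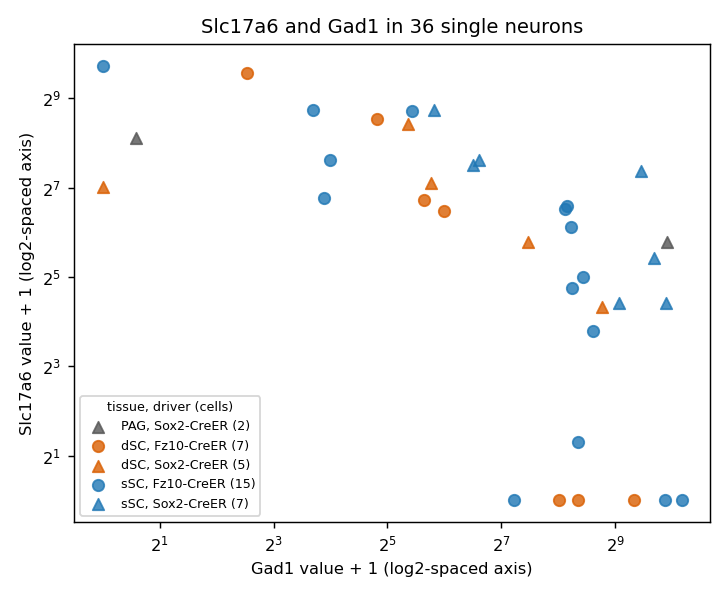
Values of Slc17a6 against Gad1, each plus 1 on log2-spaced axes, for the 36 cells, with colour for tissue and shape for driver. Cells with high Slc17a6 lie at low Gad1 and the reverse. Of the 5 cells with 100 or more of Slc17a6 together with Gad1 or Gad2, only the sSC cell of clone Q reaches this in both plotted genes (Slc17a6 at 164, Gad1 at 703).

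The clones address whether neurons from 1 progenitor share a transmitter type. Siblings often lay on opposite sides. Clone I held an sSC cell with Gad1 at 1145 and Slc17a6 listed at 0, and a dSC cell with Slc17a6 at 369.8 and Gad1 at 27.2. Clone A was the mirror of this, with Slc17a6 at 425 and Gad1 at 11.9 in the sSC cell, and Gad1 at 642 and Slc17a6 listed at 0 in the dSC cell. Clones U and N also split between a Slc17a6-rich cell (421 and 424) and a Gad1-rich cell (322 and 817). Other pairs matched: both cells of clone J were rich in Slc17a6 (763 and 849.9), and both cells of clone T in Gad1 (343 and 389.6). In all, 10 of 18 pairs had balances of opposite sign, against 9.36 under reassignment of cells (permutation p = 1). Of the others, 4 pairs were both on the GABA side and 4 both on the Slc17a6 side. Opposite signs occurred in 5 of the 9 pairs split between sSC and dSC and in 4 of the 6 pairs within sSC. The mean gap in balance between siblings was 5.76 log2 units, against 5.55 under reassignment (permutation p = 0.809, 18 pairs). Balance lay within 2 of 0 in 8 cells, so the sign is a position on a range and not a cell type. Slc32a1, with a median of 8.75, was lower than Gad1 and Gad2 and draws the balance towards the Slc17a6 side. The sSC cell of clone Q had Gad1 at 703, Gad2 at 461 and Slc17a6 at 164, yet a balance of -0.11. A cell of clone K, counted as opposite to its sibling, had -0.001 with Gad1 at 282 and Slc17a6 at 95.4. The reassigned cells were counted with the same 0 point. Of 11 pairs with both cells outside that band, 7 had opposite signs.

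**Figure D2:**
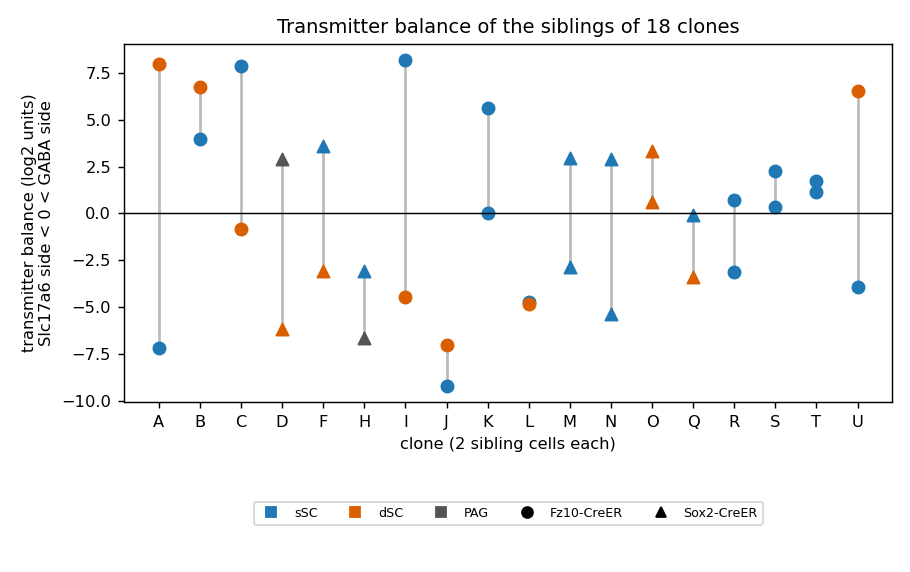
Transmitter balance in log2 units of the 2 cells of each of 18 clones, joined by a line, with colour for tissue and shape for driver. The line crosses 0 in 10 clones, and the values run from -9.22 to 8.18.

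Transmitter balance overlapped widely between the tissues. It averaged -0.09 ± 4.88 in sSC (SD, n = 16) and -0.60 ± 5.52 in dSC (SD, n = 11), a difference of 0.51 (permutation p = 0.8), or 0.24 without the clone B library (permutation p = 0.908). Balance was above 0 in 12 of 22 sSC cells and in 5 of 12 dSC cells. Within the 9 clones with both tissues the difference was 0.10, with 5 of 9 higher in sSC (exact p = 0.969). By gene, Gad1 differed by 1.24 between sSC and dSC (SE 0.97), Slc17a6 by 0.10 (SE 1.17), Gad2 by -0.16 (SE 1.07) and Slc32a1 by 0.74 (SE 0.81). None of these passed limma's test (adjusted p from 0.971 to 0.994).

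The tissue comparison asks which genes mark superficial and deep neurons. The clearest difference lay within clones, in Lst1, a gene best known from leukocytes. Lst1 was listed at 0 in the sSC cell of 8 of the 9 clones with both tissues and at 56.9 in the remaining one (clone U). The dSC siblings had values from 106 to 604, higher in 9 of 9 clones. In the other clones, 7 of 13 sSC cells had Lst1 at 1 or more (up to 307.8), and 2 of 3 dSC cells had it listed at 0. With clone as a block, Lst1 differed by -7.28 (SE 0.88, limma adjusted p = 0.00338) and was the only gene past the threshold, with 1313 at an unadjusted p under 0.05. Without the block no gene passed: limma called 0 of 14613 genes, with 754 at an unadjusted p under 0.05, and Lst1 differed by -5.06 (SE 0.95, adjusted p = 0.0714). There it was at 1 or more in 8 of 22 sSC cells and in 10 of 12 dSC cells. With the clone entered through limma's duplicateCorrelation (estimated correlation 0.0262) 0 genes passed as well, and Lst1 had the smallest adjusted p, 0.055. The blocked call also ended when the number of genes detected was added as a covariate (difference -7.13, SE 1.16, adjusted p = 0.213).

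**Figure D3:**
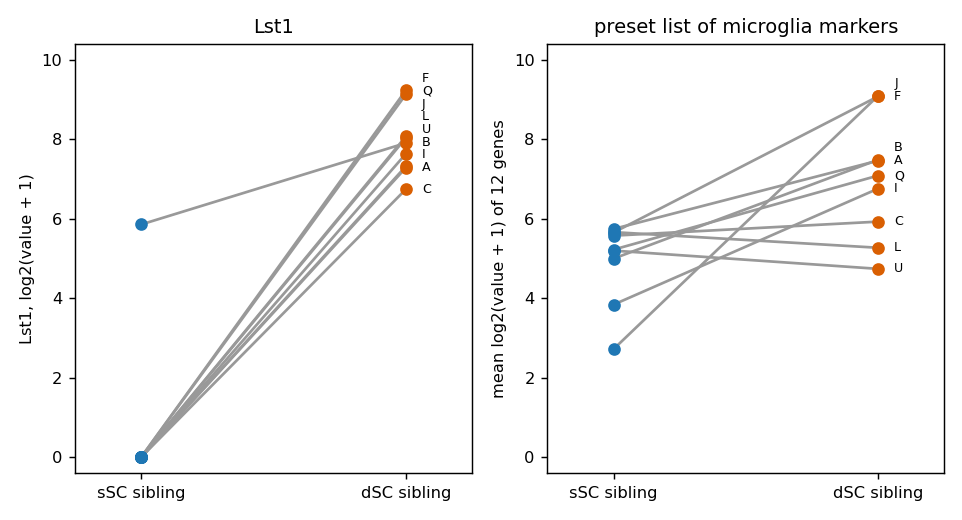
The sSC and dSC siblings of the 9 clones with both tissues, joined by lines, for Lst1 as log2(value + 1) (left) and for the mean log2(value + 1) of 12 microglia markers (right). Lst1 is higher in the dSC sibling in 9 of 9 clones and the marker mean in 7 of 9.

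Other genes with small p did not pass in either fit. Lower in sSC, Ier3, a stress-response gene, differed by -4.74 (at 1 or more in 8 of 22 sSC and 11 of 12 dSC cells) and Edem2, of the degradation pathway of the endoplasmic reticulum, by -3.70. Lgals9, a galectin, differed by -3.50, and the noncoding 9330159M07Rik by -3.01. Gm12869, antisense to Yipf1, differed by -4.27. Their adjusted p lay between 0.218 and 0.659. Higher in sSC, with an adjusted p of 0.933 each, were Saysd1 (2.86), Mapk1ip1l (2.57), Gm534 (2.58), Gm14794 (1.89), Gm47802, antisense to Zmynd11 (2.92), and Nfkbil1 (2.25). Gm534 overlaps Otx2os1 and Nfkbil1 overlaps Atp6v1g2 on the opposite strand. Among the fixed genes, Slc6a5 differed by -1.02, Slc17a7 by 0.19 and Sox2 by -0.49. Fzd10, read here as the gene behind the Fz10 driver, was at 1 or more in 2 of 22 sSC and 4 of 12 dSC cells and fell below the filter, as did Slc17a8. The median over all genes was -0.31 and moved with the scaling, the model and a single library: -0.56 at a pseudocount of 0.1, -0.10 at 10, -0.14 after quantile normalization, 0.07 with genes detected as a covariate, -0.66 with the clone block and -0.14 without the clone B library.

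No gene list passed without the block. In camera 0 of 27 lists passed (smallest adjusted p = 0.268), with 0 by fry and 0 with an estimated correlation. Immediate early genes, which follow recent activity, were lower in sSC in 20 of 22 members (median -0.76, adjusted p = 0.268), with Ier2 at -2.36 and Npas4 at -1.45, and none of them passed when adjusted over the list alone. Inhibitory lineage factors were higher in 8 of 10 members (median 0.20, adjusted p = 0.268), but in 2 of 10 with clone as a block (median -0.37). Sodium, calcium and HCN channels were lower in 23 of 27 members (median -0.50, adjusted p = 0.42), and potassium channels in 22 of 29 (median -0.36, adjusted p = 0.837). Neuropeptides were split, 8 of 16 higher (median 0.14, mean -0.04, adjusted p = 0.613). Layer-related collicular genes were higher in 6 of 14 (adjusted p = 0.69), with a median of -0.14 although camera placed the list above other genes. With clone as a block, microglia markers were lower in sSC in 12 of 12 members (median -2.02, camera adjusted p = 0.003), and that call was lost with an estimated correlation (adjusted p = 0.869, unadjusted p = 0.0643). When adjusted over the list alone 3 of 12 passed, Cd68 (-4.34) and Ctss (-2.68) among them, and none passed over all genes. Some microglial transcripts were not low in these libraries: the median of Tyrobp was 299.9 in sSC and 849 in dSC cells, and that of C1qa 189.7 and 299.5. Others were low, such as Ptprc, with a mean log2(value + 1) of 0.52 in sSC and 1.73 in dSC, and Itgam (0.605 and 1.51).

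The driver comparison asks whether progenitors labelled through Fz10-CreER and Sox2-CreER give different sSC neurons. No gene passed limma's test (0 of 14320, with 587 at an unadjusted p under 0.05 and a smallest adjusted p of 0.324). Chrac1, a subunit of a chromatin remodelling complex that overlaps Ago2 on the opposite strand, came nearest. It was at 1 or more in 6 of 15 Fz10-CreER cells and in 7 of 7 Sox2-CreER cells, a difference of -6.27 (SE 1.26). It passed only at a pseudocount of 10 (-4.10, adjusted p = 0.037). Also lower in Fz10-CreER cells were Scx (-3.06), Gm8822 (-3.69), Prrg1 (-2.86), Krt1 (-3.89) and 4930447C04Rik (-4.33), with an adjusted p of 0.38 each. Scx overlaps Bop1, and 4930447C04Rik overlaps Six6, on the opposite strand. Higher were Gm19412 (5.06, adjusted p = 0.929), AL603804.1 (3.78), A430018G15Rik (3.08), Fopnl (3.25), Gm11942 (2.60) and Trim47 (2.695), the others with an adjusted p of 1. Leaving out clone H gave 5 genes (Ints12, Slc25a20, Prrg1, Gm16312 and Gm14705) and leaving out clone F gave 1 (Gm48265). Clone H entered through 1 cell, which had 6180 genes at 1 or more, the second fewest of all cells.

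Among the transmitter genes, Gad2 differed by -2.51 (SE 1.42), Gad1 by -1.80 (SE 1.29), Slc17a6 by -1.50 (SE 1.46) and Slc6a5 by -1.94 (SE 0.74), all with an adjusted p of 1. Sox2, the gene behind the second driver, was at 1 or more in 5 of 15 Fz10-CreER and 3 of 7 Sox2-CreER cells. Of 5 measured progenitor and driver genes, Pax6 (-1.99) was lower in Fz10-CreER cells when adjusted over the list alone, and so was Vtn (-2.48) among 8 vascular and meningeal markers. Neither passed over all genes. In camera 0 of 27 lists passed (0 by fry, and 0 with an estimated correlation). Astrocyte markers were lower in Fz10-CreER cells in 13 of 13 members (median -1.27) and red blood cell markers higher in 3 of 4 (median 1.37), both with an adjusted p of 0.0734. Without the clone B library with few genes, both lists and oxidative phosphorylation passed at the preset correlation, 3 lists in all, and 0 passed with an estimated one (smallest adjusted p = 0.86). The median over all genes was -0.38, against -0.05 after quantile normalization and 0.13 with genes detected as a covariate. It also moved with single clones, to -0.146 without the clone B library and -0.78 without clone H.

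The interaction of tissue and driver rested on 1 gene. Gm17122, antisense to Coro1c, averaged 4.84 ± 5.26 in Fz10-CreER sSC (SD, n = 11 clones) and 10.19 ± 1.40 in Fz10-CreER dSC (n = 7), on the log2 scale. In Sox2-CreER clones the order was opposite, 11.05 ± 0.87 in sSC (n = 5) and 1.49 ± 2.99 in dSC (n = 4). The sSC minus dSC difference therefore differed by -14.90 between the drivers (SE 2.64, limma adjusted p = 0.0311), and 845 of 14613 genes had an unadjusted p under 0.05. Strand is not known, so reads of Coro1c can enter this value. Next, and not past the threshold, were Nol12 (-7.19, adjusted p = 0.363), Gm19938 (-7.07), Rnf149 (-7.31) and 6330418K02Rik (-8.90). In the other direction were Cldn5, of endothelial tight junctions (5.07, adjusted p = 0.749), A530017D24Rik (7.99), Lrrc39 (5.59), Mfap3l (5.12), Gm42482 (5.01) and Gm12353 (4.54). The transmitter genes did not pass (Gad1 -3.37, Gad2 -3.37 and Slc17a6 0.93). The call was lost at a pseudocount of 10, without the filter, without trend and robust, and without the clone B library (adjusted p of 0.12, 0.177, 0.142 and 0.511). With clone as a block the difference was -17.895 (SE 3.26) and the call was also lost (adjusted p = 0.638). Difference and SE grew by similar shares. Fewer residual degrees of freedom were left, as only 2 Sox2-CreER and 7 Fz10-CreER clones have both tissues.

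The clone effect asks what siblings share. Eif2s3y led, with a correlation between siblings of 0.963 (limma F test, adjusted p = 0.000277, 16 clones). Eif2s3y was above 0 in both cells of 8 clones and in neither cell of 10. Gm45016, antisense to Btbd1 (sibling correlation 0.8, adjusted p = 0.0093), and Rps3a3, a ribosomal pseudogene inside Pde4d (0.777, adjusted p = 0.0456), also passed, 3 of 15132 genes in all, with 1180 at an unadjusted p under 0.05. Next were Gm15779 (adjusted p = 0.0787), Dynlt3, a dynein light chain (0.0931), and Pvalb, the calcium buffer parvalbumin (0.16, sibling correlation 0.65). 1700021J08Rik, the globin gene Hba-a1, Gm8399, the myelin gene Cldn11 and the unnamed ENSMUSG00000118642 also had an adjusted p of 0.16. S100a10 and Josd2 had 0.184, and Rps2-ps13 and Ykt6 had 0.198. Transmitter genes did not pass: sibling correlations were -0.09 for Slc17a6, 0.079 for Gad1, 0.116 for Gad2 and -0.015 for Slc32a1 (adjusted p from 0.665 to 0.824).

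Some lists held members that passed the clone test when adjusted over the list alone. These were Pvalb and S100a10 of 13 calcium-binding proteins, Cldn11, Sox10, Mag and Mal of 12 oligodendrocyte markers, and all 4 measured globin genes (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt). Slc6a4, the serotonin transporter, and Sox2 were the others. None of these passed over all genes. Across the most variable genes, siblings correlated at 0.202 on average against 0.199 for reassigned cells (permutation p = 0.714, 18 pairs). As a check of the clone letters, the sex call from Xist and 4 Y-linked genes matched in 14 of 18 pairs against 8.31 under reassignment (one-sided permutation p = 0.00454). Xist itself was low, at 1 or more in 22 cells with a maximum of 39.5.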

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

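Chosen after the results were seen were the splits and swaps, the search for single clones, the clone block on the interaction, the fits that join the block with genes detected or leave out the clone B library, the counts of Lst1 outside the pairs, the exact tests and matched lists for microglial genes other than the blocked test of the second list, and the test of intron lengths.

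The sSC minus dSC difference of Gm17122 differed between the drivers by -14.90 (SE 2.64, limma adjusted p = 0.0311). With clone as a block it was -17.895 (SE 3.26), and the call ended (limma adjusted p = 0.638). Difference and SE grew by similar shares, and fewer residual degrees of freedom were left (7 against 23). Chance could not be excluded as the source of the unblocked call: 8 of 100 reassignments of the driver gave 1 gene or more, and the highest of the others gave 3. In the other comparisons across genes, the real tissue count was 0, so 100 of 100 splits reached it, and the highest other gave 240. The real driver count was 0, with 100 of 100 splits reaching it and 357 in the highest other. Few splits gave such counts: 1 (tissue) and 2 (driver) of 100 reached 10 or more genes, and the median of the others was 0. In those highest splits the sides differed by 3543 and 4810.0 genes detected, and whether that gap made the calls was not tested. For the clone effect, 17 of 100 reassignments reached the real count of 3, and the highest other gave 55. With clone as a block, 4 of 100 swaps of tissue within clones reached the real count of 1, the real arrangement included, with 1 in the highest other. That share is under 0.05, but the test was 1 of several chosen after the results were seen, without adjustment for their number. It therefore does not exclude chance.

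Single clones lay far from the rest of their group for 17 of the 88 small groups of values tested, where chance gives about 4.4. Values are log2(value + 1), with the nearest other clone in brackets. Among Sox2-CreER sSC clones these were Gm19412 in clone N at 3.95 (0), Trim47 in clone Q at 2.15 (0), Prrg1 in clone H at 0 (3.51) and Krt1 in clone Q at 0 (4.74). Uty in clone H was at 7.77 (2.08), Cldn5 in clone M at 1.07 (0) and Gm42482 in clone M at 0.90 (0). Among Fz10-CreER dSC clones they were A530017D24Rik in clone A at 8.46 (3.39), Mfap3l in clone C at 1.92 (0.65), Gm42482 in clone A at 0.97 (0) and Rnf149 in clone B at 0 (4.42). Among Sox2-CreER dSC clones, clone Q stood out in Uty at 5.64, Kdm5d at 5.07, Eif2s3y at 5.03 and Sox2 at 6.99. Clone O stood out in Gm17122 at 5.98 and 6330418K02Rik at 2.05. The other clones of that group were at 0 for these 6 genes. Uty, Kdm5d and Eif2s3y are Y-linked, so their values in clones Q and H may follow the sex of the clone. Eif2s3y was above 0 in both cells of clones Q and H, and at 0 in both cells of clones D, F, M, N and O. As Eif2s3y is among the genes in question, this is not separate evidence. Xist was listed at 0 in both cells of clone H. The sex of clone Q is not settled, as Xist was at 21.965 in its sSC cell and 9.862 in its dSC cell. Among all cells, 5 had Xist at 1 or more together with Eif2s3y above 0. Genes at 0 in most cells of a group can give such outlying values readily, which was not tested. Prrg1, Krt1 and Rnf149 are not of that kind, as they were at 0 only in the clone named. For Prrg1 that was the clone H cell with 6180 genes at 1 or more, and whether low detection gave its 0 was not tested.

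Lst1 was lower in the sSC sibling in 9 of 9 clones. Outside these clones the tissues did not part this way: Lst1 was at 1 or more in 7 of 13 sSC cells (up to 307.8), 4 of them at or above the lowest dSC sibling, and listed at 0 in 2 of 3 dSC cells. Within the pairs, the lower number of genes in sSC cells does not account for the difference: with clone as a block and genes detected as a covariate the difference was -7.13 (SE 1.16), against a median of 0.07 for all genes. The call itself ended there. The SE grew from 0.88 to 1.16, and the covariate took a residual degree of freedom. Without the clone B library the blocked difference was -7.24 (SE 0.92). Whether the tissues themselves differ stays open, given the cells outside the pairs.

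The mean of the microglia markers was lower in the sSC sibling in 7 of 9 clones (exact p = 0.0273), all but clones L (5.66 in sSC and 5.27 in dSC) and U (5.20 and 4.74). Lst1 is in neither microglia list. A candidate explanation is RNA of microglia taken up with the neurons, more of it with dSC cells. A second list of 20 microglial genes (19 measured), written before it was looked at, was lower in sSC in 19 of 19 (blocked median -1.61), and 0.02% of 10000 expression-matched random lists were as low. Its mean was lower in 9 of 9 clones (exact p = 0.00391). These are the same 9 pairs in which the first list was tested, so the second list is not independent of it. Fcer1g (-4.41) and Aif1 (-4.02) differed most in the second list, and no sort that would remove microglia is named in the labels. Lower detection in sSC cells cannot be told apart from this. With genes detected added to the block, the median of all genes moved from -0.66 to 0.07 and that of the first list from -2.02 to -1.62 (camera adjusted p = 0.00115 at the preset correlation, 0.598 at an estimated one), and 0.01% of the random lists were as low as the second. The preset correlation and the random lists make little or no allowance for genes that vary together. The microglia markers did so, with an estimated correlation of 0.324 with the block and no clone B library. Values at those settings therefore do not decide the question. Between clones the spread was too wide to exclude lower detection by the rule used for Lst1. With the block and genes detected, the mean difference was -1.54 (SE 0.97) for the first list and -1.28 (SE 0.795) for the second. Each lay within 2 SE of the median of all genes. Relative to the mean of all genes of a cell, the lists were lower in 6 of 9 (exact p = 0.082) and 7 of 9 clones (exact p = 0.0508).

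Part of the gene models that take 1% or more of a cell may owe their values to how intron signal was scaled. Of the 32 models, 24 had an annotated intron, and their median length was 33 bp, against 16311.5 bp in other genes, and the lowest of 10000 random sets had 3176.5 bp. The account reaches only the 17 models with 1 to 100 bp of intron, which together took a median of 19.56% of a cell. Of the others, 6 belong to the mitochondrial genome, whose genes in all took a median of 8.37%. Gm17711, with 1 bp of intron, took up to 40.6% of a cell, and Gm10800, with 95 bp, up to 21.9%. Few reads over a short intron would give a large value per length. Intron lengths came from an older build, and no biological explanation was tested.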

How the results depend on the processing

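The alternatives that removed the dominant gene models, left out the clone B library with few genes (also with an estimated correlation of the lists), used the block for the interaction, or joined the block with these or with genes detected were chosen after seeing the data. Where no cause is given, the cause was not tested.

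For sSC against dSC the count of genes went from 0 to 1 in 8 alternatives. Lst1 was that gene at a pseudocount of 10, after quantile normalization, with the clone block, with driver as a covariate, after rescaling without the dominant gene models (with and without the block) and without the clone B library with the block. In Sox2-CreER clones alone it was Gm17122. Leaving out 1 clone gave 0 to 1 genes (Ier3 without B, Lst1 without D, N, O or T) and, for the drivers, 0 to 5 (without H, and 1 without F). The drivers gave 1 gene at a pseudocount of 10. The interaction gave 0 at a pseudocount of 10, without a filter, without trend and robust, without the clone B library and with the clone block. The clone effect gave 6 genes at a pseudocount of 0.1, 60 without a filter, where more genes were tested, and 1 without trend and robust. Where it stayed at 3 the genes could differ: Eif2s3y with Gm8399 and Gm44103 at a pseudocount of 10, Eif2s3y with Rps3a3 and Mrpl34 without the clone B library, and, in clones with both siblings in sSC, Tyrobp, Cryab and Gm9812 in place of all 3.

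Lists for the tissues went from 0 to 1 with the block and to 2 with the block and either genes detected or no clone B library, microglia markers and immediate early genes. With an estimated correlation these calls were lost (microglia markers adjusted p = 0.869 with the block and 0.598 with genes detected as well, immediate early genes 0.443, and 0.726 for both with the block and no clone B library). Lists for the drivers went to 3 without the clone B library and to 0 there with an estimated correlation (smallest adjusted p = 0.86). At a pseudocount of 0.1 the similarity of whole transcriptomes turned to -0.0016, and the sibling gap in balance was 7.08, just below its reassigned mean of 7.09. Genes detected differed by -2868 with the block, past the threshold.

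For single genes, the tissue comparison held 859 values over 24 genes, of which 800 kept direction and side of the threshold, 12 newly passed and 47 reversed. The drivers held 691 over 26 genes (668, 2 and 21). The interaction held 202 over 23 genes, of which 184 were the same, 5 lost the call and 13 reversed. The clone effect held 322 over 33 genes, with 307 the same, 7 newly past and 8 lost.

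Tissue differences reversed as follows. At a pseudocount of 10 Slc17a6 was -0.06 and Gad2 0.037, and after quantile normalization -0.035 and 0.17. With the block, Ddx3y was -0.61, Uty -0.67 and Slc17a6 -0.12, and after rescaling as well -0.59, -0.64 and -0.15. Without the clone B library they were -0.65, -0.70 and -0.14, with Slc17a7 at -0.22. With the block and genes detected, Xist was 0.11, Ddx3y -0.55, Uty -0.62, Slc17a7 -0.083 and Gad2 0.96. In Sox2-CreER clones alone Xist was 1.14, Slc17a6 -0.42, Slc17a7 -0.45, Gad2 2.12 and Slc6a5 0.62, and in Fz10-CreER clones alone Uty was -0.19. With genes detected as a covariate Gad2 was 0.62 and Sox2 0.15, and without the clone B library Gad2 was 0.17. Leaving out 1 clone gave Uty -0.26 to 0.69, Kdm5d -0.515 to 0.27, Slc17a6 -0.66 to 0.78, Slc17a7 -0.034 to 0.56 and Gad2 -0.53 to 0.47.

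Driver differences reversed for Slc32a1 (-0.036) and Sox2 (0.011) at a pseudocount of 10, for Sox2 after quantile normalization (0.18) and with genes detected (0.36), and for Gad1 (0.053) and Sox2 (0.18) with sSC and dSC cells per clone. Leaving out 1 clone gave Ddx3y -0.093 to 1.83, Kdm5d -0.24 to 0.88, Slc17a7 -0.006 to 1.31, Slc32a1 -0.64 to 0.67 and Sox2 -0.71 to 0.60. In the interaction, Kdm5d was 0.054, Slc32a1 -0.02 and Sox2 0.32 at a pseudocount of 10, Slc32a1 -0.03 at 0.1, and Sox2 0.33 after quantile normalization. Without the clone B library Kdm5d, Slc32a1 and Sox2 were 0.07, -0.032 and 0.02. With the block, Uty was 1.43, Kdm5d 1.059, Slc17a7 -0.34, Slc32a1 -1.945 and Sox2 1.29. Depth is not known, so the limit it sets on low genes could not be computed.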

Other observations

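All tests in this part were chosen after the data were seen, including the association with transmitter balance.

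Genes of the developing midbrain followed transmitter balance across the 36 cells. Towards the GABA side rose Sox14 (0.47 log2 per unit of balance, SE 0.08, limma adjusted p = 0.00489), Gata3 (0.41), Otx2 (0.47) and Lhx1 (0.34), transcription factors of GABAergic lineages, with Lhx1os (0.52). The synaptic vesicle protein Synpr (0.40), the channel subunit Asic4 (0.38), Fibcd1 (0.30), Rpp25 (0.40) and Gm27199 (0.49) rose with them. Towards the Slc17a6 side were Nrn1 (-0.42), a neurite growth factor, and Cacna2d1 (-0.37), a calcium channel subunit. These 12 of 14898 genes passed, with 745 at an unadjusted p under 0.05. All 10 measured inhibitory lineage factors had positive slopes (median 0.25, camera adjusted p = 2.96e-22, and 2.43e-05 with an estimated correlation), and 8 passed adjusted over the list alone. Of 17 excitatory lineage factors 15 had negative slopes (median -0.16, camera adjusted p = 3.87e-10, and 0.000622 with an estimated correlation), and 7 passed adjusted over the list alone, Lhx2, Lhx9, Tcf7l2, Pou4f2, Ebf1, Ebf2 and Ebf3. Camera also called neuropeptides, monoamine and acetylcholine receptors, and GABA and glycine receptors, none of them with an estimated correlation.

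A hypothesis is that siblings with different transmitter markers also differ in the lineage factors of those transmitters. With clone as a block, which compares siblings, the medians were 0.34 and -0.16, and the larger estimated-correlation p of the lists was 4.03e-05, in line with this. Single genes had less support: with the block 1 gene passed, Nrn1 (adjusted p = 0.0203). Genes detected do not account for the association, since 12 of the 12 genes passed with that covariate. Of 100 reassignments of the balance among cells of a tissue 1, the real one with its 12 genes, reached that count, and the highest other gave 1 gene. Such a count was therefore rare under reassignment. The reassignments treated siblings as separate cells, and the association was chosen after the data were seen, so they do not exclude chance. Without the 2 cells farthest from the median balance 7 genes passed, 6 of them shared. Siblings enter the unblocked fit as separate cells.

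Siblings were closer than reassigned cells in some lists. The mean gap was 0.76 against 1.32 for vascular and meningeal markers, smaller than the reassigned mean in 16 of 18 pairs (permutation p = 0.0015, adjusted p over 27 lists 0.0309). For calcium-binding proteins it was 0.64 against 1.01, in 12 of 18 pairs (permutation p = 0.00229, adjusted p = 0.0309). Red blood cell markers may reach siblings from a shared animal or slice. Their gap was 2.23 against 3.37 (adjusted p = 0.0905), which leaves this undecided at 18 pairs. Lineage factors had larger gaps between siblings than reassigned cells, 1.435 against 1.246 for excitatory and 2.25 against 1.98 for inhibitory factors (adjusted p = 0.536 and 0.633).

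The 2 PAG cells, both from Sox2-CreER clones, belong to no comparison of tissues. The cell of clone D had Gad1 at 964, Gad2 at 1035, Slc17a6 at 53.7 and Sst at 7033. The cell of clone H had Slc17a6 at 278, Tac1 at 3750.3 and Gad1 at 0.51.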
